A study of Mus musculus with 24 samples.

How the data were processed

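The series measured circular RNAs in cardiac fibroblasts of male C57BL/6J mice after transverse aortic constriction (TAC), a surgical narrowing of the aorta that loads the left ventricle with pressure, or after a sham operation. Per the labels, hearts were perfused and digested on a Langendorff apparatus, fibroblast RNA was extracted with TRI Reagent and treated with DNase I, ribosomal RNA was removed with Ribo-Zero Gold, and stranded total RNA libraries were sequenced in paired-end mode on an Illumina instrument. A sort or gate on cell type is not given in the sources used here. The table holds 24 libraries: 4 sham and 4 TAC libraries at 1 week, 5 sham and 4 TAC libraries at 4 weeks, and 4 sham and 3 TAC libraries at 8 weeks. Columns were matched to samples by the sample descriptions, because the numbers in some column names of the 4-week and 8-week sham groups differ from the replicate numbers of the titles; replicates are numbered here as in the titles.

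The authors' table lists 1717 circular RNAs by the coordinates of their back-splice junction, the join of the end of a downstream exon to the start of an upstream one. The submitters' processing notes name FastQC, Trimmomatic, STAR and the mouse build mm10 without versions; the circular RNA caller's settings, its filters and the way the values were normalized are not given in the sources used here. The deposited values are a normalized signal of junction reads and not raw reads: in every column each value minus 0.01 was a whole multiple of a step fixed for that library, so that whole reads had been divided by a library factor and 0.01 had been added. With that offset removed, 100% of the values came out whole within 0.001 of a read. One read was worth 0.642 to 1.57 normalized reads, and the deposited factors differed from factors proportional to total junction reads by at most 5.18%. Values are given below as normalized reads with the offset removed.

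Junctions were annotated with the GENCODE mouse annotation of the same build. The host gene was the gene on the junction's strand whose exon boundaries matched both ends of the junction, or failing that one end, or that overlapped it; 1666 junctions had both ends at exon boundaries of the host, 36 had 1 end there and 15 had none, and 22 had more than 1 candidate host. Exon numbers count along the annotated transcript that matched. The filter fixed in advance, at least 2 reads in at least 3 libraries, removed no circular RNA, so all 1717 were tested.

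A count-based test had been planned, on the assumption that the table held raw reads. The values are normalized, so the main test was instead limma 3.58.1 in R 4.3.3, with an intensity trend in its empirical Bayes step, on log2(normalized reads + 0.5). All 24 libraries entered a fit with 6 groups and no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all 1717 circular RNAs for each comparison, with calls at an adjusted p of 0.05. Log2 fold changes are on the log2(value + 0.5) scale, which understates the change of scarce circular RNAs, and errors of log2 fold changes are standard errors (SE). Where every library of a group had 0 reads, the fold is the observed mean of the other group over a floor of 3 reads for the whole group. The words "at least" refer to that floor only. They leave out the error of the other group's mean, which rested on as few as 8 reads, so the true fold can be smaller. The floors cover counting error only and not the spread between libraries. The comparisons were TAC against sham at each time, their average with equal weight, the differences of the TAC effect between times, and the sham groups between times. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. No 2 libraries of a group had identical values, and each of the 37 pairs within groups differed by more than counting noise (largest chi-square p 0.00106). The comparisons, gene lists, naming rule, filter and most of the other settings were fixed before the data were examined.

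Host gene lists covered extracellular matrix (17 circular RNAs of 13 host genes), myofibroblast contractile and adhesion genes (20 of 10), TGF-beta, BMP and SMAD signalling (16 of 10), Wnt and Hippo signalling (21 of 13), receptor tyrosine kinase and MAPK signalling (27 of 18), resting cardiac fibroblast markers (16 of 10), cardiomyocyte markers (15 of 10), endothelial markers (11 of 7), mural cell markers (2 of 2), macrophage and other leukocyte markers (27 of 11), cell cycle (6 of 4), chromatin and transcription regulators (71 of 38), RNA-binding and splicing factors (34 of 17) and widely reported circular RNA host genes (59 of 31). Lists with at least 5 circular RNAs were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, all from limma, and adjusted over the lists; the mural list was too small. Chromatin regulators and widely reported hosts shared 2 circular RNAs. Single values per library, such as junction reads or the summed normalized reads of a list, were compared with two-sided exact permutation tests at each time and, over all times, with 100000 permutations within time.

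The circular RNAs to name were, for each comparison, up to 12 higher and 12 lower circular RNAs past the threshold with the smallest p, filled up to 12 with the smallest unadjusted p where fewer passed, given as values that did not pass. To these were added the 10 with the highest mean share of reads, up to 3 of each list, and the circular RNAs of Smad4. Not all that this rule selects are reported here.

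On simulated reads drawn from the means and depths of these libraries, with 100 circular RNAs changed 2-fold and 100 (99 where a draw lost 1) changed 4-fold, the fit recovered 1%, 4% and 3% of the 2-fold and 12%, 19% and 14% of the 4-fold changes at 1, 4 and 8 weeks. In the averaged comparison it recovered 22% and 64.6%, with 2 false calls among 88. For the differences between times it recovered 0% of the 2-fold changes and 1% to 5% of the 4-fold changes; the sham comparisons recovered 1% to 5% and 9% to 24%. The table held 3595 to 9146 junction reads per library and a median of 44 reads per circular RNA over all 24 libraries, so that 20.7% of the values were 0.

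Alternatives changed the pseudocount, the scaling, the read minimum, the test (limma-voom with library quality weights on the whole reads), the libraries in the fit, the threshold, the summing of circular RNAs per host gene, and left out each library in turn. The pseudocounts 0.1 and 1, the scaling by the trimmed mean of M-values (TMM, coded from its published definition), the restriction to junctions at exon boundaries, the test of each list between times, the tests of summed list reads, the tests of lists with each library left out and the cardiomyocyte list without Ttn were chosen after the data were examined. The planned count-based test and the filter and factors that belong to it were not run, because the deposited values are normalized and their whole reads were inferred. Among the tests of single circular RNAs, limma-voom alone took these inferred reads as counts. The other scalings, the junction totals, the thinnings, the read minimums and the floors were also computed from the inferred reads. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.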

Results

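Circular RNAs, closed transcripts formed when a downstream splice site joins an upstream one, were measured in cardiac fibroblasts of sham-operated and TAC mice at 1, 4 and 8 weeks after surgery. The series concerns the roles of circular RNA in cardiac fibrosis. The table held 1717 circular RNAs of 1187 host genes, and 320 hosts had at least 2. Most joined coding exons: 1363 lay in coding exons alone, 269 in coding and untranslated exons and 18 in untranslated exons, with a median span of 6241 bp and 3 exons. A read was present in all 24 libraries for 277 of them. Depth was low, at 3595 to 9146 junction reads per library and a median of 2 reads per circular RNA and library.

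The most abundant circular RNA in every library was that of Nfix, a nuclear factor I transcription factor, made of exon 2 (chromosome 8, 84771784 to 84772315, mm10). It took a mean of 3.12% of the junction reads, and measured 196 ± 75.5 normalized reads in sham (SD, n = 4) and 140 ± 34.7 in TAC (n = 4) at 1 week. Its averaged change did not pass the test (log2 fold change -0.25 ± 0.09 SE, adjusted p = 0.172; 0.0186 without sham 1-week replicate 3). The next was exon 2 of Med13l, a subunit of the Mediator kinase module, at 1.08%. The other 8 of the 10 most abundant came from Mmp15, Rnf169, Lrch3, Adgre1, Nfkb1, Fbxw4, Rad52 and Elf2, at 0.502% to 0.679% of the reads each; of these only Nfkb1 passed a test between TAC and sham. The averaged log2 changes of the 7 that did not ranged from -0.22 for Adgre1, which encodes the macrophage receptor F4/80, to 0.31 for Lrch3.

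At 1 week, circular RNAs of Tns3 and Ezh2 were among those higher in TAC libraries, and circular RNAs of the cardiac muscle genes Ryr2 and Ttn were lower. With no sort on cell type given, a change between libraries cannot be assigned to fibroblasts rather than to other cells in them. Tns3 encodes tensin 3, which links integrins to actin, and its circular RNA of exons 18 to 20 (chromosome 11, 8478225 to 8479665) rose from 2.91 ± 1.95 to 14.5 ± 5.35 normalized reads (n = 4 each; log2 fold change 2.48 ± 0.55, adjusted p = 0.0068; 1.70 without sham replicate 3, which had 0 reads, and not called). Ezh2, the methyltransferase of Polycomb repressive complex 2, rose from 12.5 ± 5.12 to 38.4 ± 12.5 in its circular RNA of exons 2 and 3 (chromosome 6, 47576536 to 47577667; 1.60 ± 0.39, adjusted p = 0.0113). Ryr2, the calcium release channel of the cardiac sarcoplasmic reticulum, fell from 10.7 ± 6.05 to 0.722 ± 0.919 in exons 59 to 62 (chromosome 13, 11680966 to 11688013; -3.39 ± 0.65, adjusted p = 0.000528). Ttn, the giant elastic protein of the sarcomere, fell from 31.3 ± 19.9 to 9.19 ± 2.48 in exons 85 to 118 (chromosome 2, 76857904 to 76881839; -1.55 ± 0.36, adjusted p = 0.0075).

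In all, limma called 25 of the 1717 circular RNAs at 1 week, 13 higher and 12 lower, and 201 had an unadjusted p under 0.05 against 85.9 by chance. Itgbl1, which encodes a secreted protein with integrin-beta-like repeats, had no reads in the sham libraries and 6.46 ± 6.46 normalized reads in TAC in its circular RNA of exons 3 to 7 (chromosome 14, 123827752 to 123857579), at least 6.95-fold higher. Cdkn3, a phosphatase that acts on cyclin-dependent kinases, was at least 3.82-fold higher (chromosome 14, 46762528 to 46768897, exons 2 to 6; TAC 3.55 ± 1.59). Mettl9, Tcf20, Gigyf2, Nlrp5-ps, Setbp1, Pakap and a further Tns3 circular RNA of exons 14 to 16 rose by log2 values of 1.39 (Gigyf2) to 2.37 (Pakap). Without sham replicate 1, Mettl9 moved from 1.83 to 0.53 (adjusted p = 0.619), Tcf20 from 2.04 to 1.21 (0.306) and Nlrp5-ps from 2.31 to 1.67 (0.197). Nlrp5-ps was at 1.67 without sham replicate 2 too (0.234), and without sham replicate 3 it was at 3.16 and Mettl9 at 2.48, both called. Exons 17 to 19 of Bub1b, a kinase of the mitotic spindle checkpoint (chromosome 2, 118631759 to 118635277), measured 4.29 ± 0.949 in sham and 18.8 ± 11.8 in TAC (1.85, adjusted p = 0.0459).

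Among the lower circular RNAs, Ablim3, an actin-binding LIM protein, fell from 10.1 ± 3.7 to 1.97 ± 1.79 normalized reads (chromosome 18, 61839690 to 61857185, exons 4 to 8; log2 fold change -2.46 ± 0.59, adjusted p = 0.0095). Tlk1, Atxn1, Dock1, Epn2, Agap1 and Bcl2l13 fell by 1.31 (Tlk1) to 2.40 (Agap1) on the log2 scale. With a TAC library left out, Ablim3 was at -1.84 (replicate 3), Bcl2l13 at -1.30 against -1.98 (replicate 4) and Epn2 at -1.58 against -2.19 (replicate 1), none called, and Dock1 was at -2.80 against -2.16 without sham replicate 3 and called. Sptlc2, a subunit of serine palmitoyltransferase, had 2.78 ± 0.321 normalized reads in sham (9 reads in all) and none in TAC in exons 5 and 6, at least 3.45-fold lower against the floor. A pair of short junctions inside the pseudogene Gm28437 (chromosome 1, 24613551 to 24613613 and 24613561 to 24613622) was lower too, the first by -2.51 (adjusted p = 0.042; -1.74 and not called without sham replicate 3, -3.67 and called without sham replicate 1) and the second at least 5.92-fold. Over both intervals the pseudogene is 100% identical to the mitochondrial transcript mt-Co3, so these reads cannot be assigned to either copy.

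Of the 25 calls at 1 week, Ryr2 was kept when each of the 8 libraries was left out in turn (largest adjusted p 0.00868, without TAC replicate 3). Ablim3 (0.132) and Itgbl1 (0.0763) were lost without TAC replicate 3 alone, Tns3 exons 18 to 20 without sham replicate 3 alone (0.096), Ttn without sham replicate 2 or 3 (up to 0.096), and Ezh2 without TAC replicate 2 or 4 (up to 0.0629). The other 19 were lost in at least 3 of the 8 fits, and Bub1b in all 8. The number called was 6 without sham replicate 2, 8 without TAC replicate 3, 9 without TAC replicate 4 and 12 without TAC replicate 2, and it was 10 with limma-voom and 4 when the 1-week libraries alone entered the fit.

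**Figure D1:**
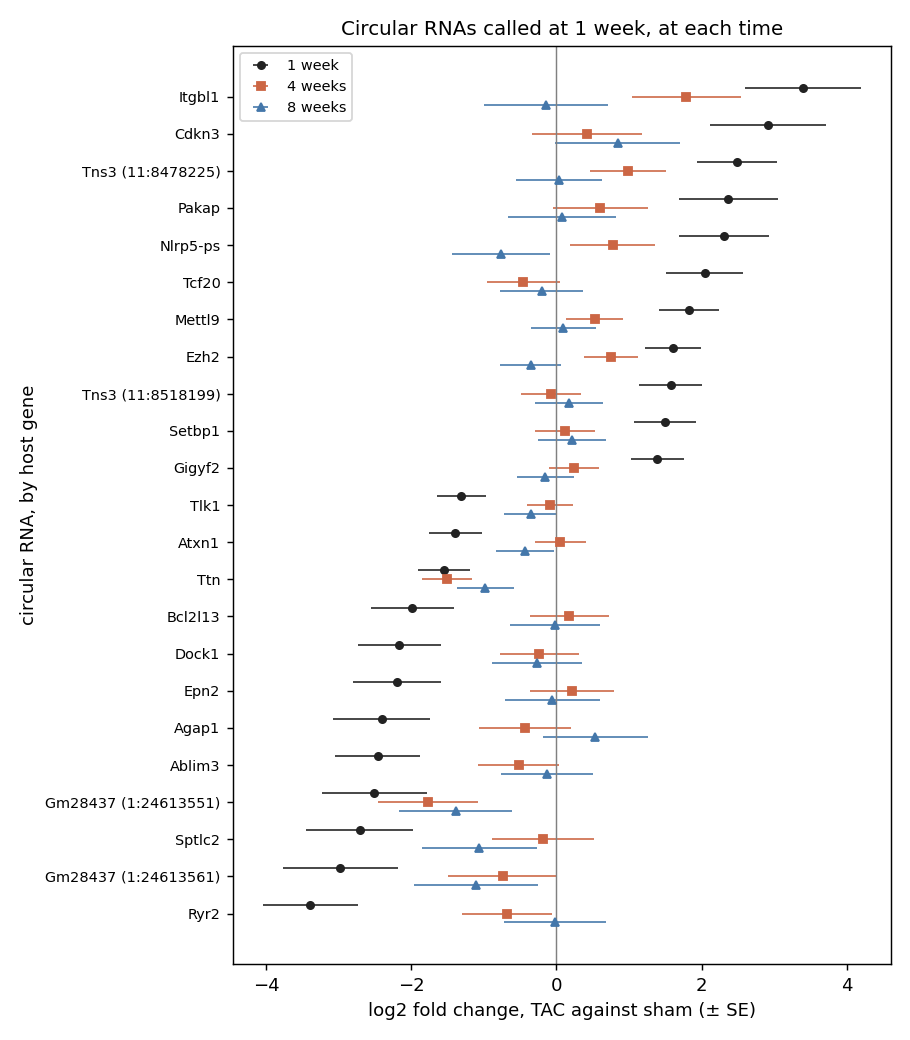
Log2 fold change of TAC against sham (x axis, with bars of 1 SE) at 1, 4 and 8 weeks for 23 of the 25 circular RNAs called at 1 week, each named by its host gene (y axis). Ryr2 lies at -3.39 at 1 week and -0.02 at 8 weeks, while Ttn exons 85 to 118 lies at -1.55, -1.51 and -0.98 at 1, 4 and 8 weeks.

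Of the host gene lists, cardiomyocyte markers changed at 1 week: 11 of the 15 circular RNAs, from 10 of the 54 genes listed, had negative fold changes, and 2 passed over all circular RNAs (camera adjusted p = 7.95e-05; adjusted p = 0.169 with an estimated correlation and 0.0628 by fry). Adjusted over the list alone, 6 were lower and 1, Atp2a2, was higher; Atp2a2 encodes a calcium pump that fibroblasts also express. At the preset correlation, the cardiomyocyte call was kept without each of the 8 libraries (8.94e-06 to 0.0353). It was also kept with the Ttn circular RNAs taken out of the list (0.0103). These fits were not repeated with the estimated correlation, which was 0.194 for this list. The summed normalized reads of the list were 88.9 ± 49.5 in sham and 32.7 ± 6.74 in TAC, a ratio of 0.368 (exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow, and 0.0476 adjusted over the 3 times). Cell cycle genes had 5 of 6 circular RNAs with positive fold changes and a summed level 3.06 times that of sham (29.3 ± 9.45 against 9.56 ± 4.28; exact p = 0.0286, 0.0857 adjusted), but the list did not pass camera (0.089; adjusted p = 0.169 with an estimated correlation). By fry, which asks whether a list moves one way on balance, cell cycle genes and resting cardiac fibroblast markers were both higher (adjusted p = 0.0442 for each). The resting fibroblast list did not pass camera (adjusted p = 0.28, and 0.33 with an estimated correlation).

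The 11 other lists tested at 1 week, like the cell cycle list, did not pass camera (adjusted p 0.089 to 0.961 over these 12 lists). In the extracellular matrix list 10 circular RNAs had positive and 7 negative fold changes, with 0 called over all circular RNAs and 1 higher and 1 lower adjusted over the list alone; its median was positive while its mean and test were negative. The endothelial list had a negative median and test and a positive mean. The macrophage and other leukocyte list had 19 positive and 8 negative fold changes and no call, and in sham replicate 1 its summed normalized reads were 194.7 against 78.1 to 97.2 in the other 3 sham libraries.

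At 4 weeks, the 2 circular RNAs called were both of Ttn and both lower in TAC. Exons 85 to 118 fell from 31.3 ± 12 normalized reads in sham (SD, n = 5) to 11.1 ± 4.53 in TAC (n = 4; log2 fold change -1.51 ± 0.34, adjusted p = 0.0232). Exons 84 to 118 (chromosome 2, 76857904 to 76884197) fell from 12.6 ± 5.06 to 2.52 ± 1.73 (-2.23 ± 0.53, adjusted p = 0.0274). Both were lower in 4 of 4 TAC libraries, with no overlap between the groups. An unadjusted p under 0.05 was found for 137 circular RNAs against 85.9 by chance, 88 of them higher and 49 lower. The median log2 fold change of all circular RNAs was 0.228, 0.117 and 0.0753 at pseudocounts of 0.1, 0.5 and 1. It was 0.0376 over those with a mean of at least 5 reads, so the general lean towards higher values depends on how scarce circular RNAs are handled.

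The circular RNAs next in order at 4 weeks did not pass. Malat1, a nuclear long noncoding RNA, had 3.90 ± 2.04 normalized reads in sham and none in TAC at a junction of 45 bp (chromosome 19, 5801899 to 5801943), at least 7.12-fold lower (adjusted p = 0.0509). Pik3c2a, a class II phosphoinositide kinase, had a log2 fold change of 2.74 (0.0509), the ephrin ligand gene Efnb2 2.23 (0.0672) and the endosomal gene Rabep1 1.98 (0.077). Exon 2 of Med13l was at -0.79 (0.1) and Ikzf1, a transcription factor of lymphoid cells, at -1.63 (0.146). Vav3, Usp3, Phf21a and Fancl were at 1.07 (Phf21a) to 2.07 (Fancl), with adjusted p of 0.133 to 0.281. With 1 of the 24 libraries left out, 1-week libraries of the shared fit included, Malat1, Pik3c2a and Efnb2 passed in 5 fits each, Rabep1 in 4, Med13l in 3 and Vav3 in 1; each of the first 5 passed without sham 1-week replicate 1 (0.0267 to 0.0291).

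Both Ttn calls at 4 weeks were lost without sham replicate 1, 3 or 4 or TAC replicate 3, and that of exons 84 to 118 also without TAC replicate 2 (largest adjusted p 0.54 and 0.484, without TAC replicate 3). Without sham replicate 1 or 4 or TAC replicate 3 no circular RNA was called, without TAC replicate 2 there was 1, without sham replicate 3 there were 3, none of them among the 2, and without sham replicate 2 or 5 there were 4; TMM scaling called 6 (3 higher and 3 lower against 0 and 2), a pseudocount of 1 called 6 and of 0.1 called 0, and limma-voom and the 4-week libraries alone called 14 each. TMM moved the median log2 fold change of all circular RNAs at 4 weeks from 0.12 to 0.22, a shift of 0.10; relative to that median, Ttn exons 85 to 118 was at -1.62 as deposited and -1.59 with TMM, and exons 84 to 118 at -2.35 and -2.33.

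Cardiomyocyte markers, macrophage and other leukocyte markers and cell cycle genes were each lower as lists at 4 weeks. The cardiomyocyte list had 11 of 15 negative fold changes (camera adjusted p = 0.00726; adjusted p = 0.344 with an estimated correlation), with 0 higher and 2 lower adjusted over the list alone. Its summed reads were 76.3 ± 39.5 in sham and 35.4 ± 10.3 in TAC, a ratio of 0.464 (exact p = 0.0317, 0.0476 adjusted). The leukocyte list had 18 of 27 negative fold changes (0.00726; adjusted p = 0.31 with an estimated correlation), with 0 called over all circular RNAs and 3 lower adjusted over the list alone. The cell cycle list had 5 of 6 negative fold changes and no single call (0.0372; adjusted p = 0.242 with an estimated correlation). By fry 0 of the 13 lists passed at 4 weeks. The cardiomyocyte call was lost without sham replicate 3 (0.376) or TAC replicate 3 (0.0555) and without the Ttn circular RNAs (0.571), the leukocyte call without sham replicate 2 (0.0546) or TAC replicate 3 (0.237), and the cell cycle call without sham replicate 1, 2, 3 or 4 (0.0693, 0.0551, 0.114 and 0.146), without TAC replicate 3 or 4 (0.0555 and 0.294) and when Ttn left the cardiomyocyte list (0.0558). The other 10 lists did not pass (0.13 to 0.962), and for the extracellular matrix, myofibroblast and TGF-beta lists the mean was positive and the test negative, with a negative median in the first 2.

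The 4-week TAC libraries were also the deepest. They held 7980 ± 940 junction reads (n = 4) against 5666 ± 1188 in sham (n = 5; exact permutation p = 0.0159, the smallest possible, 0.0476 adjusted over the 3 times). At 1 week the totals were 5207 ± 1097 in TAC and 4681 ± 725 in sham (exact p = 0.457), and at 8 weeks 5698 ± 1023 and 5493 ± 417 (exact p = 0.743; 3 against 4 libraries cannot go below 0.0571). Over all times the permutation p within time was 0.0179. With every library thinned to 3595 reads, the number of circular RNAs detected did not differ between TAC and sham past the threshold: 1180 ± 16.9 and 1147 ± 55.4 at 1 week, 1185 ± 16.8 and 1168 ± 7.89 at 4 weeks, and 1171 ± 12.9 and 1185 ± 8.34 at 8 weeks (exact p = 0.343, 0.0794 and 0.229; permutation p = 0.314 over all times). The difference in junction reads at 8 weeks, 205, was -311.5 without TAC replicate 3.

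At 8 weeks, limma called 0 circular RNAs between TAC (n = 3) and sham (n = 4) as deposited, 0 by limma-voom and 0 under the other scalings, pseudocounts and sets of libraries, while 0 to 1 were called over 20 thinnings to 3595 reads; 104 had an unadjusted p under 0.05 against 85.9 by chance. The smallest adjusted p, 0.459, was that of 7 circular RNAs. Exons 8 to 10 of Cpeb3, a cytoplasmic polyadenylation element binding protein, measured 4.41 ± 1.42 normalized reads in sham and 0.341 ± 0.59 in TAC (chromosome 19, 37044522 to 37068291; log2 fold change -2.71 ± 0.80). The kinase gene Snrk was at -2.29 (-1.39 without TAC replicate 3), Nav1, a list member of the resting fibroblast markers, at 2.65 and Aff3 at 1.96 (1.24 without sham replicate 3). Trim33, Mlip and Asxl2 had no reads in TAC and were at least 3.09-fold, 3.56-fold and 3.14-fold lower. Lrp6, Tmbim6, Epb41l2, Atf7ip and Zbtb46 came next and did not pass either. None of the 13 lists passed camera (0.12 for cardiomyocyte markers to 0.971), and the summed reads of cardiomyocyte markers were 63.1 ± 7.00 in TAC and 103.9 ± 32 in sham (ratio 0.607, exact p = 0.114). For the leukocyte, cell cycle and RNA-binding lists the median, mean and test differed in sign at 8 weeks.

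Averaged over the 3 times, with 11 TAC and 13 sham libraries, circular RNAs of Cpeb3 and Med13l, 2 of Ttn and a junction placed in Gm28437, whose reads cannot be told from those of mt-Co3, were lower in TAC. Those of Creb3l2, Nfkb1, Aff3, Svep1, Tns3 and Itgbl1 were higher. Ttn exons 85 to 118 had a log2 fold change of -1.34 ± 0.21 (adjusted p = 6.42e-07) and exons 84 to 118 of -1.71 ± 0.33 (0.000204), each lower in 11 of 11 TAC libraries than the sham mean of its time. Cpeb3 exons 8 to 10 fell by 2.05 ± 0.43 (0.00148, 10 of 11 libraries), and Gm28437 (24613551 to 24613613) by 1.89 ± 0.42 (0.00388, 11 of 11). Creb3l2, an endoplasmic reticulum stress transcription factor, rose by 1.45 ± 0.35 in exons 3 to 8 (chromosome 6, 37353557 to 37364143; adjusted p = 0.0082, 11 of 11 libraries), from 3.15 ± 2.21 to 12.7 ± 4.95 normalized reads at 1 week. Svep1, an extracellular matrix protein, rose by 1.22 ± 0.30 in exons 2 and 3 (chromosome 4, 58175931 to 58179707; 0.0124, 11 of 11).

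Nfkb1, the p50 subunit gene of NF-kappa-B, rose by 0.76 ± 0.18 (adjusted p = 0.0082, 11 of 11 libraries) and was the most abundant of those that rose, with 25.8 ± 11.7 normalized reads in sham and 45.1 ± 9.29 in TAC at 1 week. Aff3, a nuclear protein related to transcription elongation factors, rose by 1.39 ± 0.34 (0.0098, 11 of 11), Tns3 exons 18 to 20 by 1.17 ± 0.32 (0.0485, 10 of 11) and Itgbl1 by 1.68 ± 0.46 (0.0485, 9 of 11). Exon 2 of Med13l (chromosome 5, 118593333 to 118593570) fell by 0.58 ± 0.14 (0.0082, 10 of 11). Ryr2 exons 59 to 62 did not pass (-1.36 ± 0.38, adjusted p = 0.0559, 8 of 11 libraries; it passed in 7 of the 24 fits with a library left out). In all 11 circular RNAs were called, 6 higher and 5 lower, while median-of-ratios scaling gave 5 higher and 8 lower; 170 had an unadjusted p under 0.05 against 85.9 by chance.

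The calls of both Ttn circular RNAs, Cpeb3 and Gm28437 were kept without each of the 24 libraries in turn. The other 7 were lost without TAC 8-week replicate 1, which left 4 calls; Aff3 was also lost without sham 8-week replicate 3 (up to 0.093), Svep1 without sham 8-week replicate 1 (up to 0.0931), Tns3 in 18 and Itgbl1 in 13 of the 24 fits, while 17 circular RNAs were called without sham 1-week replicate 1. A pseudocount of 0.1 left 5 calls, and limma-voom gave 21.

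**Figure D2:**
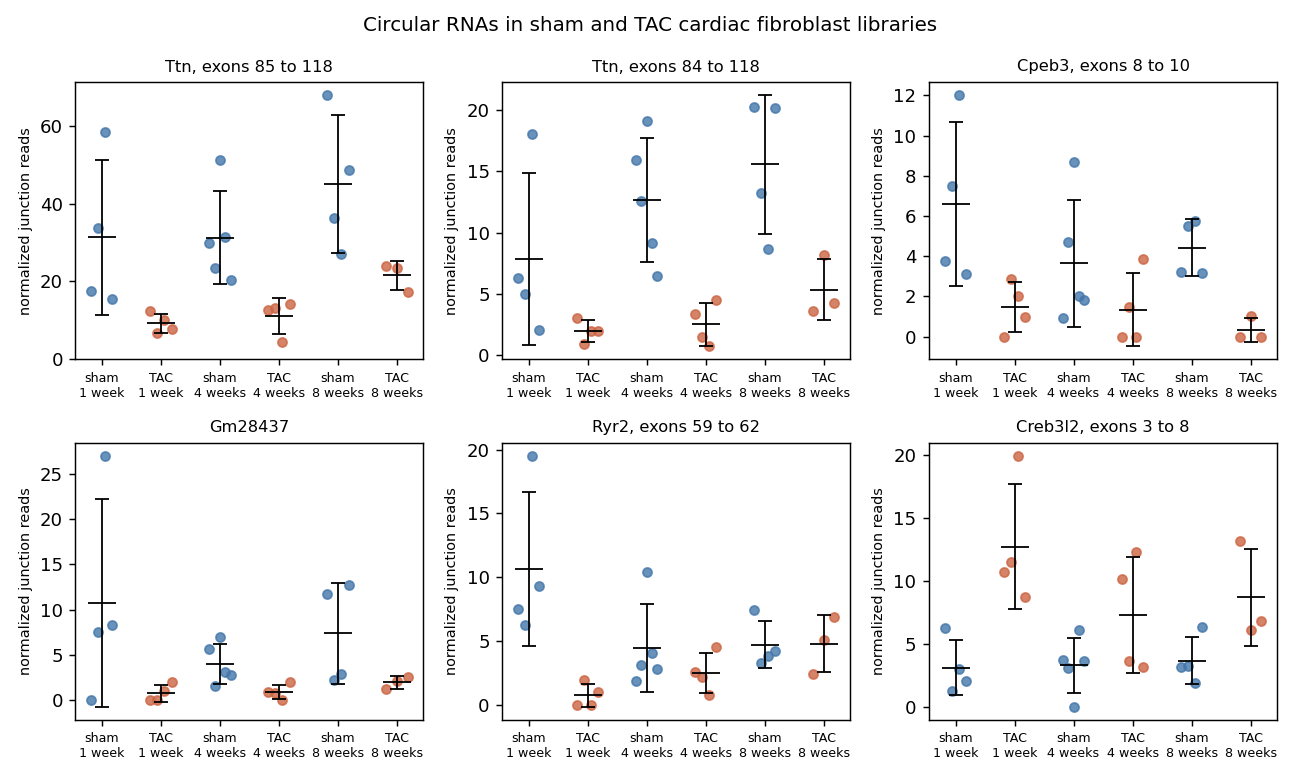
Normalized junction reads (y axis) of 6 circular RNAs in each library (points) of the 6 groups (x axis), with the mean and bars of 1 SD. Ttn exons 85 to 118 measured 31.3, 31.3 and 45 in sham and 9.19, 11.1 and 21.5 in TAC at 1, 4 and 8 weeks.

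As a list, cardiomyocyte markers were lower in the averaged comparison, with 12 of 15 circular RNAs at negative fold changes and 2 called over all circular RNAs (camera adjusted p = 1.33e-07; adjusted p = 0.0649 with an estimated correlation; fry 0.041). Adjusted over the list alone, 6 were lower and 1 higher. At the preset correlation of 0.01 the call was kept without each library (7.99e-09 to 2.03e-05) and without the Ttn circular RNAs (0.0193). These fits were not repeated with the estimated correlation of 0.194, so they show stability under the preset alone. After Ttn, whose exons 85 to 118 averaged 25.3 normalized reads over all libraries, the list's most abundant members were Cacna1c (5.47, averaged log2 fold change 0.53), Myocd (4.89, -0.49) and Ryr2 exons 59 to 62 (4.62, -1.36). Over all times the summed reads of the list differed with a permutation p of 0.00017.

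None of the other 12 lists passed camera in the averaged comparison. The adjusted p was 0.258 for resting cardiac fibroblast markers and 0.462 for endothelial markers. It was 0.707 for the myofibroblast, TGF-beta, Wnt and Hippo, leukocyte, chromatin and widely reported host lists, and 0.927 for the extracellular matrix, receptor tyrosine kinase, cell cycle and RNA-binding lists. Calls over all circular RNAs in these lists were Svep1 in the extracellular matrix list, Aff3 in the leukocyte list and Med13l in the chromatin list. Adjusted over the list alone there were 2 higher of the resting fibroblast markers, 4 higher and 3 lower chromatin regulators, 1 higher each of the extracellular matrix and leukocyte lists, and 0 in the others. By fry, resting cardiac fibroblast markers were higher (0.0199). The Wnt and Hippo, chromatin and RNA-binding lists had a median, mean and test that differed in sign. The 2 mural cell markers, too few to test, were Abcc9 at -0.25 ± 0.38 and Ano1 at -0.26 ± 0.47.

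**Figure D3:**
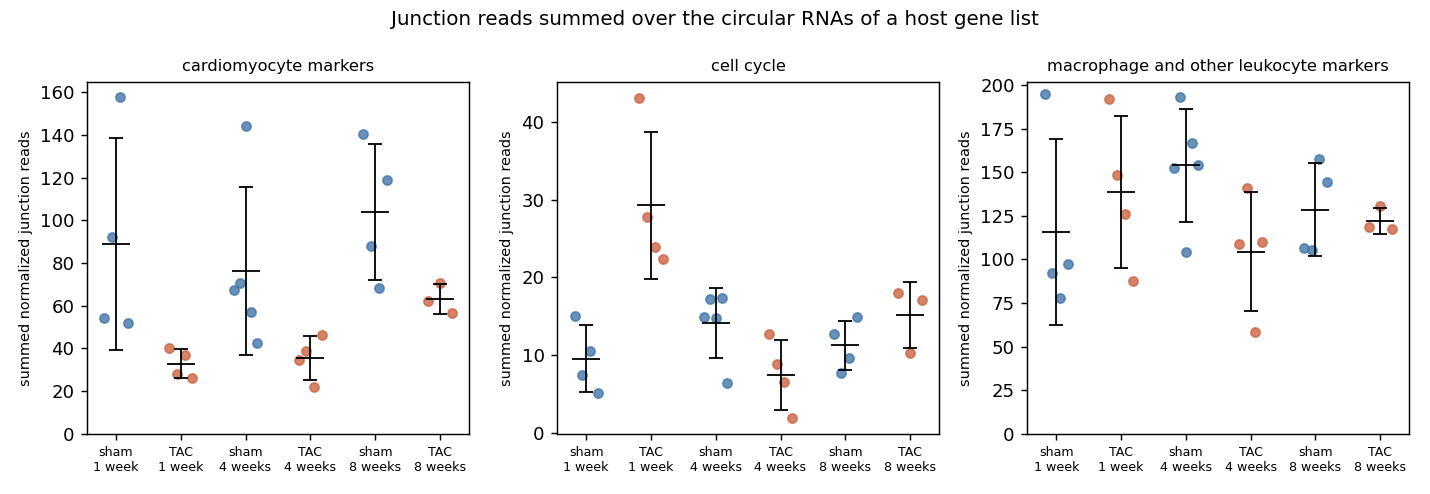
Summed normalized junction reads (y axis) of the cardiomyocyte, cell cycle and macrophage and other leukocyte lists in each library (points) of the 6 groups (x axis), with the mean and bars of 1 SD. Cell cycle sums at 1 week averaged 9.56 in sham and 29.3 in TAC.

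Smad4, the common mediator of TGF-beta and BMP signals, hosted 5 circular RNAs. None passed in the averaged comparison, with log2 fold changes from -0.15 ± 0.45 for exons 2 to 4 to 0.71 ± 0.47 for exons 5 to 10. The most abundant, exons 5 to 8 (chromosome 18, 73657195 to 73662867), measured 11.6 ± 2.77 normalized reads in sham and 6.93 ± 1.74 in TAC at 1 week and 8.62 ± 4.65 and 11.3 ± 3.66 at 8 weeks (averaged -0.03 ± 0.28; adjusted p = 0.985).

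Whether the TAC effect itself differed between times was tested as an interaction. For single circular RNAs limma called 0 between 4 and 1 weeks, 0 between 8 and 1 weeks and 0 between 8 and 4 weeks; 138, 148 and 109 had an unadjusted p under 0.05, and limma-voom called 0, 0 and 2. The smallest adjusted p were 0.0658, 0.0557 and 0.193. Between 8 and 1 weeks 8 were called without sham 1-week replicate 3, 6 without TAC 1-week replicate 1, 2 without TAC 1-week replicate 2, and 1 without sham 1-week replicate 4 or sham 8-week replicate 3. Between 4 and 1 weeks 1 was called without sham 1-week replicate 1, TAC 1-week replicate 4, or sham 4-week replicate 3 or 5. TMM moved the median difference between 8 and 4 weeks from -0.11 to -0.26, a shift of -0.15. For the lists, in a test chosen after the data were examined, cell cycle genes (camera adjusted p = 0.00121; adjusted p = 0.0152 with an estimated correlation) and leukocyte markers (0.00142; adjusted p = 0.175 with an estimated correlation) had a lower TAC effect at 4 weeks than at 1 week. The other lists did not pass between 4 and 1 weeks (0.474 to 0.907), and no list did between 8 and 1 weeks (0.298 to 0.958) or 8 and 4 weeks (0.301 to 0.989).

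Across circular RNAs, which are not independent replicates, no correlation of fold changes between times passed after adjustment over the 3 pairs of times: Pearson r was 0.131 at 1 and 4 weeks (Spearman 0.122; permutation p = 0.0297, 0.0891 adjusted), 0.00722 at 1 and 8 weeks (p = 0.921) and 0.0141 at 4 and 8 weeks (p = 0.653). Each p came from 100 permutations of the labels within time and is a coarse estimate. The 3 times share no libraries. Circular RNAs of the same host moved together slightly more often than random pairings: of 888 pairs in 320 hosts, 56% had averaged fold changes of the same sign, against 50.7% in random pairings matched on level (95% of which lay between 47.4% and 53.9%). Hosts with several circular RNAs gave several dependent pairs, which the random pairings did not keep, so that range may be too narrow.

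Among the sham libraries, which track time after the operation and age without pressure overload, 2 circular RNAs were called between 8 and 1 weeks, both higher at 8 weeks. Ash1l, a histone methyltransferase, had no reads at 1 week and 6.76 ± 5.76 normalized reads at 8 weeks (chromosome 3, 89001773 to 89007877, exons 4 and 5), at least 7.28-fold higher (adjusted p = 0.0117, 4 of 4 libraries). Strn3, a striatin family scaffold of a phosphatase complex, rose from 1.78 ± 1.36 to 10.9 ± 2.97 (chromosome 12, 51647994 to 51661713, exons 2 to 7; 2.62 ± 0.60, adjusted p = 0.0144). Neither passed without sham 8-week replicate 1 or 3, which left no call. Strn3 was also lost without sham 8-week replicate 4, which left 1 call, and without sham 1-week replicate 2 (2.00, adjusted p = 0.457, its largest). The largest for Ash1l was 0.216, without sham 8-week replicate 1. Without sham 1-week replicate 3 there were 4 calls; limma-voom called 1 and the sham libraries of these times alone called 0. Crebrf, Clip2, Dysf, Lrp6, Zfp609, Mettl9, Lonp2, Atf7ip, Slc8a1 and Ptms did not pass (0.0856 to 0.241). Crebrf, at 1.90, was at 0.93 without sham 1-week replicate 2 and passed without replicate 3 (2.66) or 4 (2.49). Mettl9, at 1.36, was at 0.06 without sham 1-week replicate 1 and passed without replicate 3 (2.01), and Clip2 passed without replicate 2.

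Between 4 and 1 weeks limma called 0 circular RNAs in sham, with 130 at an unadjusted p under 0.05 and 0 by limma-voom; 4 were called without sham 1-week replicate 1, 2 without replicate 3, and 1 without replicate 4 or sham 4-week replicate 3. Tcf20 was at 2.03 ± 0.50 (adjusted p = 0.101; 1.20 without sham 1-week replicate 1, and past the threshold without sham 1-week replicate 3 or 4 or sham 4-week replicate 3), Zfp609, host of a widely reported circular RNA, at 1.71 ± 0.46 (0.189) and Erbin at -2.06 ± 0.58 (0.194). Zfp609, Erbin and Zfp141 (2.30, 0.209) passed without sham 1-week replicate 1. Mtss1, Gigyf2, Efnb2, Tlk1, Lrp6 and Vav3 did not pass (0.209 to 0.221). Dennd1a was at least 3.86-fold lower at 4 weeks and did not pass. Between 8 and 4 weeks 0 were called, with 119 at an unadjusted p under 0.05 and 0 by limma-voom, and the smallest adjusted p was that of Efnb2 (2.21 ± 0.59, 0.371). Atf7ip, Rabep1, Rasa2, Fbxw7, Vav3, Crebrf, Vapa, Pbrm1, Nav1 and Malat1 followed (0.377 to 0.62).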

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

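The tests of the lists between times and of the other junctions inside exons, and the share of thinnings asked for at 1 week, were chosen only after the results were seen.

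Ttn exons 85 to 118 and 84 to 118 were lower in TAC libraries in the averaged comparison and Ryr2 exons 59 to 62 at 1 week (averaged adjusted p 0.0559, up to 0.171 with a library left out), in fibroblasts for which the sources used here give no sort against cardiomyocytes. The other circular RNAs of Ttn and Ryr2 in the cardiomyocyte list were not called in these comparisons. For Ttn, a difference in depth was argued against, since with every library thinned to 3595 reads the averaged log2 fold change of Ttn exons 85 to 118 had a median of -1.275 over 20 thinnings (-1.61 to -1.02, SE 0.235), and so was a single library, since its largest adjusted p with each library left out was 2.73e-05. Less cardiomyocyte RNA carried into the TAC libraries is a candidate explanation: within groups, 12 circular RNAs of 9 other cardiomyocyte genes rose and fell with Ttn exons 85 to 118 (mean residual correlation 0.331, against a median of -0.0222 and an upper 95% limit of 0.117 for random circular RNAs of the same level), among them Ryr2 exons 59 to 62 (0.388); Ttn exons 84 to 118 did too (0.808). Atp2a2 followed Ttn within groups (0.405) but had an averaged log2 fold change of 1.33. A change inside the fibroblasts after TAC stays open and was not tested.

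Both short junctions in the pseudogene Gm28437 were lower in TAC libraries. A general fall of junctions inside exons as large as that of Gm28437 was argued against over the 3 times. The other 13 junctions with no end at an exon boundary had a median averaged log2 fold change of -0.23 (SE 0.19, 7 lower and 6 higher) against -1.89. However, the summed reads of all 15, the 2 of Gm28437 included, were lower in TAC over all times (permutation p within time 0.0178, not adjusted). At 4 weeks their ratio was 0.438 (exact p = 0.0159, 0.0476 adjusted), so a smaller general fall is not excluded. Reads of the mitochondrial transcript mt-Co3 placed on its nuclear copy are a candidate source, because both intervals, of 63 and 62 bp, are 100% identical to mt-Co3. Less carried-over cardiomyocyte RNA, rich in mitochondrial transcripts, is in line with a mean residual correlation of 0.588 of the pair with Ttn exons 85 to 118 (random upper 95% limit 0.31). A change of the pseudogene's own transcript in fibroblasts stays open and was not tested.

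In the main test more circular RNAs were called at 1 week (25) than at 4 (2) or 8 weeks (0). The order of 1 and 4 weeks was the reverse with limma-voom (10 and 14 called). It was also the reverse in fits of the compared libraries alone (4 and 14), so the excess at 1 week depends on the test and on the libraries in the fit. Sham 1-week replicate 1, which lies apart from the rest, was argued against as the cause of the count alone, since 20 were called without it. However, 6 were called without sham replicate 2, 8 without TAC replicate 3, 9 without TAC replicate 4 and 12 without TAC replicate 2. The 20 were partly other circular RNAs than the 25. Agap1, Atxn1, Bcl2l13, Bub1b, Cdkn3, Dock1, Epn2, Mettl9, Nlrp5-ps and Tcf20 were lost without sham replicate 1, so that library bears on which circular RNAs were called. With all libraries thinned to the same total, the median count was 4 at 1 week (0 to 9 over 20 thinnings) and 1 at 4 weeks (0 to 6), and in 15 of the 20 thinnings the 1-week count was more than 1.5 times the 4-week count; the ranges overlap, so an effect of lower depth at 1 week and a larger response at that time cannot be told apart. An earlier response to TAC stays open: with the values as deposited and all libraries 0 circular RNAs passed a test of the difference between times, and 0 to 8 did in other fits.

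Other splits of the same libraries into groups of the same sizes show how often each count arises without the real grouping. At 1 week the real split gave the most calls (1 of 35 splits, 25 against at most 19). That is the smallest share that 35 splits can give, and it makes no allowance for the other comparisons. It argues against chance but does not exclude it. The 19 came from the split of replicates 1 and 2 of both arms against replicates 3 and 4, which points to a structure of the samples that the labels do not name. At 4 weeks 3 of 100 splits gave 2 or more (at most 5), and in the averaged comparison 1 of 100 gave 11 or more (at most 7 otherwise). With the same limit, these shares argue against chance for both counts but do not exclude it. At 8 weeks all 35 splits gave 0 or more (at most 1). For the differences between times all 100 splits gave at least the real 0, with at most 7 between 4 and 1 weeks, 4 between 8 and 1 weeks and 2 between 8 and 4 weeks. In sham, 7 of 35 splits gave as many calls as the 2 between 8 and 1 weeks (at most 8, with sham 1-week replicates 1 and 2 exchanged for 8-week replicates 1 and 4), so chance is not excluded. All 100 splits did for the 0 between 4 and 1 weeks and the 0 between 8 and 4 weeks (at most 2). The 16 calls reached between 4 and 1 weeks point to a structure of the samples. That split exchanged only sham 1-week replicate 1 and sham 4-week replicate 3. After this exchange the sets also lay apart in summed leukocyte reads (78.1 to 104.1 against 152.3 to 194.7 normalized reads). Whether leukocyte content accounts for these calls was not tested.

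For the lists the same count was made on the camera p. The cardiomyocyte list had the smallest p in the real split at 1 week (1 of 35, 6.12e-06 against 2.02e-05) and was matched in 2 of 100 in the averaged comparison (1.02e-08 against 2.9e-09). These shares argue against chance for this list taken by itself. They do not exclude it, since they make no allowance for its choice as the list that passed among 13. At 4 weeks it was matched in 26 of 100 (0.000955 against 3.74e-08), the leukocyte list in 10 of 100 (0.00112 against 4.91e-05) and the cell cycle list in 12 of 100 (0.00858 against 5.97e-05), so chance is not excluded for the 3 lists at that time. Between 4 and 1 weeks the leukocyte list was matched in 2 of 100 (0.000219 against 5.38e-05) and the cell cycle list in 1 of 100 (9.27e-05 against 0.000174). These 2 lists were taken because they alone passed among 13 lists and 3 differences, so these shares do not exclude chance.

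The TAC effect of the leukocyte list and of the cell cycle list differed between 4 and 1 weeks in a test of the difference itself (camera adjusted p = 0.00142 and 0.00121); with an estimated correlation the leukocyte list did not pass (0.175) and the cell cycle list did (0.0152). The cell cycle list has 6 circular RNAs, 3 of them of Bub1b.

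Among 432 groups of 4 or 5 libraries tested, 44 held a library far from the others by Dixon's test, against 21.6 by chance, about 1 in 20 groups; 1 read is worth 0.642 to 1.57, so many of these values rest on 1 or 2 reads. In sham 1-week replicate 1 the summed leukocyte reads were 194.7 (others 78.1 to 97.2), Adgre1 74.1 (19.6 to 22.5), Lrp5 6.28 (0) and Ano1 1.26 (0), and the library lay at 34.1 on the first principal component, where the others lay between -22.7 and 21.4. Sham 4-week replicate 3 had summed cardiomyocyte reads of 144 (42.4 to 70.7), sham 4-week replicate 5 summed cell cycle reads of 6.45 (14.8 to 17.3), and TAC 4-week replicate 3 Ttn exons 85 to 118 at 4.36 (12.7 to 14.1) and Tgfbr2 at 2.18 (5.07 to 5.78).

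The other highest values in 1-week libraries were Bnc2 at 5.75 in TAC replicate 2 and Lrp5 at 0.998 in TAC replicate 3, and in sham F13a1 at 1.25 in replicate 2, Adgrf5 at 1.5 in replicate 3, and Atf7ip at 1.03, Lrp6 at 1.03 and Smad4 exons 2 to 8 at 3.10 in replicate 4. The lowest were Mtss1 at 1.25 in sham replicate 2, Tns3 exons 18 to 20 at 0 in sham replicate 3, and in TAC Bub1b exon 9 at 0 in replicate 1, Ptk2 exons 2 to 4 at 0 in replicate 3 and Svep1 exons 2 and 3 at 7.78 in replicate 4.

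In 4-week sham libraries the highest were Mtss1 at 0.934 in replicate 1, Adgrf5 at 1.74 and Atf7ip at 0.868 in replicate 3, and Ano1 at 5.53, Fbxw7 at 1.84, Ptk2 exons 3 to 7 at 0.921 and Svep1 exons 18 to 21 at 0.921 in replicate 5, and the lowest were Svep1 exons 2 and 3 at 1.57 in replicate 2 and Creb3l2 at 0 in replicate 3. In 4-week TAC libraries the highest were Abcc9 at 6.76 and Asxl1 at 4.23 in replicate 1, F13a1 at 0.734 in replicate 2 and Insr at 1.28 in replicate 4.

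In 8-week sham libraries the highest were Asxl2 at 6.38 and Snrk at 13.8 in replicate 1, Bub1b exon 9 at 1.10, Itgbl1 at 3.30, Lrp5 at 3.30 and Rad52 at 40.7 in replicate 2, and Nav1 at 0.962 and Smad4 exons 5 to 10 at 0.962 in replicate 3. The lowest were Rabep1 at 4.40 and Rock1 at 0 in replicate 2 and Ror1 at 0 in replicate 4.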

How the results depend on the processing

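The pseudocounts, TMM scaling, the restriction to exon boundaries and the list tests without Ttn or with a library left out were chosen after the data were seen; the cause of each difference below was not tested unless stated. Counts of called circular RNAs are given where they moved over 1.5 times from 25 (1 week), 2 (4 weeks), 0 (8 weeks), 11 (averaged), 0 (each difference between times) and 0, 2 and 0 (sham 4 and 1, 8 and 1, 8 and 4 weeks). With a pseudocount of 0.1 the 4-week count was 0 and the averaged count 5; with 1 the 4-week count was 6 and that between 8 and 1 weeks 2. TMM gave 6 at 4 weeks. A mean of at least 5 reads, which tests fewer circular RNAs, gave 1 between sham at 4 and 1 weeks. Limma-voom gave 10 at 1 week, 14 at 4 weeks, 21 averaged, 2 between 8 and 4 weeks and 1 between sham at 8 and 1 weeks. Fits of the compared libraries alone, which have fewer libraries to estimate the spread, gave 4, 14 and 0 at 1 week, 4 weeks and between sham at 8 and 1 weeks. Sums per host gene gave 1 at 4 weeks, 2 between 4 and 1 weeks and 1 between sham at 8 and 1 weeks. An adjusted p of 0.10 gave 40, 6 and 18 at 1 week, 4 weeks and averaged, and 1 and 2 between 4 and 1 and 8 and 1 weeks.

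Leaving out each library gave 6 to 32 calls at 1 week, 0 to 4 at 4 weeks, 4 to 17 averaged, 0 to 1 between 4 and 1 weeks, 0 to 8 between 8 and 1 weeks, and 0 to 4 between sham at 4 and 1 and at 8 and 1 weeks. The lists called numbered 1 to 3 at 1 week (3 without sham replicate 1), 0 to 3 at 4 weeks (0 without TAC replicate 3, 1 without sham replicate 2 or 3) and 0 to 1 at 8 weeks (1 without sham replicate 3), against 1, 3 and 0. With an estimated correlation 0 lists were called at 1 week, 4 weeks and averaged, by fry 2, 0 and 2, and with Ttn left out of the cardiomyocyte list 1 at 4 weeks. The difference in junction reads at 8 weeks, 205, ran from -311.5 (without TAC replicate 3) to 711.5, and that in thinned detection at 4 weeks, 17.2, from 9.86 to 23.5 (without TAC replicate 2; exact p = 0.0357, not adjusted over the 3 times). Without thinning, detection at 4 weeks differed by 147.1, and by 237.5 at 2 reads, where the TAC libraries are deeper; at 8 weeks the 2-read difference was 7.58 against -13.8 thinned. Over circular RNAs with a mean of at least 5 reads the correlation of effects was 0.285 between 1 and 4 weeks and 0.0952 between 1 and 8 weeks, and 68.4% of pairs of one host had the same sign, against 55.6% in random pairings of that level (95% between 39.5% and 71.1%), so with 38 pairs it no longer passed.

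The replicate numbers did not pair single libraries: the correlation of deviations of same-numbered sham and TAC libraries was 0.0222 to 0.135 at 1 week, -0.0765 to 0.0429 at 4 weeks and -4.33e-05 to 0.0658 at 8 weeks, and not every library correlated best with its own number. At 1 week the numbers did track a structure shared by both arms. Sham and TAC libraries correlated positively within replicates 1 and 2 and within replicates 3 and 4 (0.018 to 0.135). Across these sets every correlation was negative (-0.119 to -0.012). Deviations from a group mean sum to 0 in each arm, so positive values within the sets force negative ones across them on balance. The sets are also those of a split of the same libraries described above, so these correlations are not separate support for it. With the replicate block 4 were called at 4 weeks, 1 between 4 and 1 weeks and 3 between 8 and 1 weeks, while 30 at 1 week and 9 averaged stayed within 1.5 times. Of the named circular RNAs in their comparisons (143 in all), 133 kept direction and side of the threshold with TMM, 138 with median-of-ratios factors, 142 with total reads, 117 with limma-voom, 129 and 134 with the 2 pseudocounts and 138 with the block. Fits of the compared libraries alone kept fewest, 53 of the 84 that they cover, while 22 lost their call and 9 gained one. Averaged changes that turned sign were not called in these fits: Elf2 (0.00884 with total reads, 0.0453 with TMM, 0.0405 without 4-week sham replicates 1 and 2, -0.0488 to 0.0598 with a library left out), Smad4 exons 6 to 8 (0.00589 with TMM, 0.0963 without those 2 libraries, -0.245 to 0.336), Smad4 exons 5 to 8 (0.0114 with TMM, 0.0176 with the block, -0.209 to 0.0557), Smad4 exons 2 to 4 (-0.406 to 0.106), Mmp15 (-0.222 to 0.0352), Rnf169 (-0.00252 to 0.118) and Rad52 (-0.129 to 0.00738). The filter of 2 reads in 3 libraries and no filter tested the same circular RNAs. The count-based test, its own filter and its trimmed-mean factors with pairing of singletons were not run. Depth limits the rest: of 100 simulated 2-fold changes the fit recovered 1, 4 and 3 at 1, 4 and 8 weeks.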

Other observations

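The tests of summed reads and of change in either direction given here were chosen only after the data were seen, while the lists were fixed before. The resting cardiac fibroblast list did not pass camera in the averaged comparison (adjusted p = 0.258), with 10 circular RNAs at positive and 6 at negative fold changes. Its summed normalized reads were 39.3 ± 7.80 in TAC and 29.8 ± 9.02 in sham at 1 week (n = 4 each), 34.6 ± 3.44 and 32.2 ± 8.21 at 4 weeks, and 37.2 ± 7.04 and 28.1 ± 6.07 at 8 weeks (exact p = 0.171, 0.603 and 0.114; permutation p = 0.0292 over all times, not adjusted over lists), while the summed cardiomyocyte reads of TAC were 0.368, 0.464 and 0.607 times those of sham. Bnc2, a zinc finger protein of fibroblasts, had an averaged log2 fold change of 1.5 ± 0.47 (adjusted p = 0.135; 0.0402 without TAC 8-week replicate 2) and Tshz2, a zinc finger homeobox gene, 1.05 ± 0.41 (0.255, higher in 11 of 11 TAC libraries), while Abca8b was at -0.93, a Nav1 circular RNA at -0.56 and Abca6 at -0.47. By fry's test of change in either direction, which does not compare a list with other genes, the averaged adjusted p was 0.000789 for this list, 0.00115 for chromatin regulators and 3.07e-05 for cardiomyocyte markers. Among chromatin regulators, Asxl1, a partner of a Polycomb deubiquitinase, was at -1.17 ± 0.34 (0.0718; past the threshold without sham 1-week replicate 1 or TAC 8-week replicate 2) and Ezh2 at 0.67 ± 0.23 (0.17), neither past the threshold with all libraries.

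Endothelial markers summed to 28.7 ± 6.22 normalized reads in TAC and 19.3 ± 4.48 in sham at 4 weeks, a ratio of 1.49 (exact p = 0.0476, 0.143 adjusted over the 3 times). Pecam1, the platelet and endothelial adhesion molecule, measured 9.72 ± 1.66 and 5.20 ± 2.30 in its circular RNA of exons 8 to 13, while at 4 weeks Flt1 was at -0.91, another Pecam1 circular RNA at -0.42, St6galnac3 at -0.29 and Tek at -0.13. Junctions with no end at an exon boundary, 15 in all with the 2 of Gm28437 and others of Rn7sk and Malat1, summed to 17.1 ± 6.33 in TAC and 39.1 ± 9.24 in sham at 4 weeks (ratio 0.438, exact p = 0.0159, 0.0476 adjusted), to 26.9 ± 12.7 and 42.3 ± 22.6 at 1 week (exact p = 0.314) and to 31.3 ± 1.20 and 32.1 ± 8.17 at 8 weeks (exact p = 0.914). Over all times the permutation p within time of these sums was 0.0178, not adjusted.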
